A study of Mus musculus with 32 samples.

How the data were processed

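Transcript levels were measured by RNA sequencing in 32 libraries of mouse 1-cell and 2-cell embryos. Per the labels' protocols, total RNA libraries were made from embryo lysates with a stranded SMARTer kit and are reverse-stranded. PolyA libraries were made with SMARTer Ultra Low Input cDNA synthesis and Nextera XT, which do not mark strand. Reads of a gene and of an antisense or overlapping gene therefore cannot be separated in the polyA table. The labels' descriptions give the polyA libraries as single embryos. The labels do not say whether replicates came from separate animals or collections, so a p-value measures the spread between these libraries, which may be partly technical. Replicate numbers were not treated as pairs, since libraries with the same number did not deviate from their groups together (r from -0.04 to 0.12 across genes in total RNA and from -0.18 to 0.08 in polyA RNA). They are the numbers of the titles, and for some polyA libraries the descriptions give another embryo number. Sheet numbers in the descriptions repeat between the arms and stages, so the libraries may come from several sequencing runs. The labels name no batch, and none was modelled.

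The deposited tables hold FPKM, 1 value per gene and library, and per the submitters' processing notes the authors aligned reads with HISAT2 2.1.0 to mm10 and assembled and quantified them with StringTie 1.3.3b. The annotation, filters and strand setting are not given in the sources used here. Each table lists 46078 genes, and no library repeated another. FPKM totals differed between libraries, so no common total had been imposed, and without counts the depth of each library and the counting error of each value are unknown. Gene positions and types come from GENCODE M21 on mm10, in which 45229 gene identifiers (98.2%) were found.

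From these values log2(FPKM + 1) was computed, with a pseudocount of 1. Genes with at least 1 FPKM in at least 2 libraries of a table were tested, which left 15068 genes in total RNA and 18506 in polyA RNA. All 16 libraries of a table were fitted together with 1 mean per group in limma 3.58.1 (R 4.3.3, statmod 1.5.0), with empirical Bayes moderation using the trend and robust options. Each gene thus had 1 spread for both stages. Total RNA replicates correlated at r of at least 0.98 at the 1-cell stage and at 0.935 to 0.96 at the 2-cell stage. The shared spread may therefore be too wide for 1-cell and too narrow for 2-cell comparisons. Counts at these stages are not directly comparable. The 17 contrasts were m-z+ against control in each arm and stage, m-z- against m-z+ in each arm, each mutant group against WT, 2-cell against 1-cell in each genotype, and the difference between those stage changes in each arm. Tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over the genes tested in a contrast, and a gene passed below 0.05. Errors of log2 changes are limma standard errors, and errors of FPKM are standard deviations between libraries. Differences between the Dppa2 and Dppa4 arms were tested as contrasts of contrasts in the same fits. Checked on data simulated from the group means, with 100 genes changed per fold size, the test recovered 37% of 2-fold and 80% of 4-fold changes for Dppa2 m-z+ against control at the 2-cell stage, and 38% and 87% at the 1-cell stage. The shares were 32% and 83%, and 39% and 83%, for Dppa4 m-z+ against control at the 1-cell and 2-cell stages. In polyA RNA they were 0% and 49% for m-z- against m-z+ in the Dppa2 arm and 1% and 40% in the Dppa4 arm. Against WT they were 0% for 2-fold changes. For 4-fold changes against WT they were 16% and 12% in Dppa4 m-z+ and m-z-, and 13% and 10% in Dppa2 m-z+ and labelled Dppa2 m-z- embryos. The changed genes were drawn from those above 2 on the log2(FPKM + 1) scale in the reference group, with independent noise. The shares do not hold for genes at lower levels. The noise had 1 spread per gene for both stages, so the shares may be too high for 2-cell and too low for 1-cell comparisons. Both fold sizes were planted in the same run, more changed genes than passed between real genotypes. That makes the adjusted threshold easier to pass, for changed and unchanged genes alike. Unchanged genes called numbered 7 and 9 for Dppa2 m-z+ against control at the 1-cell and 2-cell stages, and 6 and 10 for Dppa4. They numbered 9 and 1 for m-z- against m-z+ in the Dppa2 and Dppa4 arms.

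The 21 gene lists were 2-cell genes, the Obox family, maternal transcripts, ribosome biogenesis, ribosomal proteins, translation factors, splicing, proteasome, heat shock, preimplantation factors, germline genes, chromatin and DNA methylation, p53 response, imprinted genes, locus neighbours, cumulus and granulosa markers, sperm transcripts, blood cells, Y-linked genes, mitochondrially encoded genes and cell cycle. They were tested with camera at a preset correlation of 0.01 and again with the correlation estimated from the residuals. Lists with at least 5 measured members were tested, 20 in total RNA, where only 3 blood cell genes were measured, and 21 in polyA RNA. P-values were adjusted over the lists of a contrast. Activated and cleared genes were those changing by at least 2 on the log2 scale and passing between stages, taken from WT polyA libraries for total RNA contrasts and from both total RNA control arms for polyA contrasts. The lists, the tests, the grouping and the rule for naming genes were chosen before the data were examined.

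Named genes followed that rule. Dppa2 and Dppa4 were always given. For mutant comparisons, up to 10 genes with the largest rise and 10 with the largest fall were eligible among those that passed with groups that did not overlap, and where fewer than 5 passed in a direction, the 5 with the smallest p were eligible as values. Up to 4 members of each list with the highest mean FPKM and any member that passed were eligible too, and for stage changes the 4 members with the largest change that passed in controls. Predicted models were counted but not named, except where the text says so.

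Alternatives planned at the same time were a pseudocount of 0.1, no filter on low values, TPM scaling, median-ratio scaling, array weights, a replicate block, a fit of only the compared libraries, leaving out each library in turn, the estimated correlation, and activated and cleared genes taken at a log2 change of 1. Alternatives chosen after seeing the data were the restriction to gene models of at least 200 bases, the lists and sets without labelled Dppa2 m-z- replicate 3, the contrasts between arms, and the lists with the Dppa2-arm polyA labels exchanged. Where a group was left with 1 library, it was assumed to vary like the others. The libraries labelled Dppa2 m-z- are named by their label throughout, since their Dppa2 RNA did not show the loss that the label states. Fits between the total RNA and polyA tables were left out, because the kits differ.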

Results

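Transcript levels were measured in mouse embryos at the late 1-cell stage (12 hours post fertilization) and the late 2-cell stage (28 hours), between which the embryo's own genome starts to be transcribed. The embryos carried mutations of Dppa2 or Dppa4, neighbouring genes for a pair of SAP-domain nuclear proteins of early embryos. In the labels, m stands for the maternal and z for the zygotic allele, so m+z+ embryos are controls, m-z+ embryos lack the maternal supply, and m-z- embryos lack both. Total RNA was sequenced in 16 libraries in 8 groups of 2, with m+z+ and m-z+ embryos at each stage in a Dppa2 arm and a Dppa4 arm. PolyA RNA was sequenced in 16 libraries in 6 groups: 2 WT 1-cell, 2 WT 2-cell, and 3 each of 2-cell m-z+ and m-z- embryos per arm. The Dppa2 arm had a mixed B6/DBA background, and the Dppa4 arm and the WT embryos were B6. The tables hold FPKM, so the sequencing depth of a library is unknown. FPKM summed to between 412115 and 629583 per total RNA library and between 539978 and 675241 per polyA library. Genes at 1 FPKM or more numbered 10706 to 13071 and 10842 to 13916. Libraries of the same group correlated across genes at r = 0.935 to 0.987 in total RNA and 0.862 to 0.973 in polyA RNA, where genes are not independent replicates.

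The targeted genes were examined first, in every library. Dppa2 (ENSMUSG00000072419, mm10, chromosome 16, 48303908 to 48319723, forward strand) was supplied by the mother: Dppa2 RNA stood at 32.3 and 32.7 FPKM in the 1-cell controls of its arm and at 9.38 and 9.52 FPKM in the m-z+ embryos. This fall was -1.68 (SE 0.16) on the log2 scale, with an adjusted p of 0.000701 in limma. At the 2-cell stage Dppa2 stood at 49.7 and 53 FPKM in controls and 44.8 and 59.2 FPKM in m-z+ embryos, a log2 difference of 0.01. In the Dppa4 arm, Dppa2 measured 47.7 and 51.1 FPKM in 1-cell controls, 60.2 and 50.4 FPKM in 1-cell m-z+, 49.5 and 49.5 FPKM in 2-cell controls, and 45.5 and 44.1 FPKM in 2-cell m-z+ embryos. In polyA RNA, WT embryos held 134 and 94.2 FPKM of Dppa2 at the 1-cell and 123 and 69.6 FPKM at the 2-cell stage. The 3 Dppa2 m-z+ libraries held 92.4, 87.4 and 63.2 FPKM. The 3 libraries labelled Dppa2 m-z- held 155, 130 and 76.5 FPKM, so the genotype in their label was not visible as a loss of Dppa2 RNA. Their mean was 120.5 ± 40.1 FPKM (SD, n = 3) against 81.0 ± 15.6 FPKM (n = 3), a log2 difference of 0.53 (SE 0.37, limma adjusted p = 0.756). Gene-level FPKM does not separate a mutant transcript from an intact one. Every direction given for these 3 libraries rests on that label. Dppa4 m-z+ embryos held 232, 91.2 and 111 FPKM of Dppa2, and Dppa4 m-z- embryos 46.2, 48.4 and 47.7 FPKM (log2 difference -1.47, SE 0.37, limma adjusted p = 0.481).

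Dppa4 (ENSMUSG00000058550, chromosome 16, 48283733 to 48294237) was low at the 1-cell stage and high at the 2-cell stage, in contrast to Dppa2. In the Dppa4 arm, 1-cell controls held 4.37 and 6.92 FPKM and 1-cell m-z+ embryos 1.13 and 0 FPKM, a log2 difference of -2.16 (SE 0.39) that did not pass (limma adjusted p = 0.369). At the 2-cell stage the controls held 30.1 and 17.6 FPKM and m-z+ embryos 25.5 and 20.3 FPKM (log2 difference -0.02). In the Dppa2 arm, Dppa4 stood at 3.52 and 5.16 FPKM in 1-cell controls, 6.39 and 5.81 FPKM in 1-cell m-z+, 63.4 and 58.3 FPKM in 2-cell controls, and 42.7 and 80.4 FPKM in 2-cell m-z+ embryos. PolyA libraries gave 4.13 and 5.68 FPKM in WT 1-cell, 201 and 184 FPKM in WT 2-cell, 155, 152 and 125 FPKM in Dppa4 m-z+, and 0, 0 and 0.15 FPKM in Dppa4 m-z- embryos. The loss in Dppa4 m-z- embryos was -7.11 (SE 0.30, limma adjusted p = 3.00e-10). Dppa2 m-z+ libraries held 201, 354 and 207 FPKM of Dppa4, and those labelled Dppa2 m-z- held 353, 321 and 221 FPKM.

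**Figure D1:**
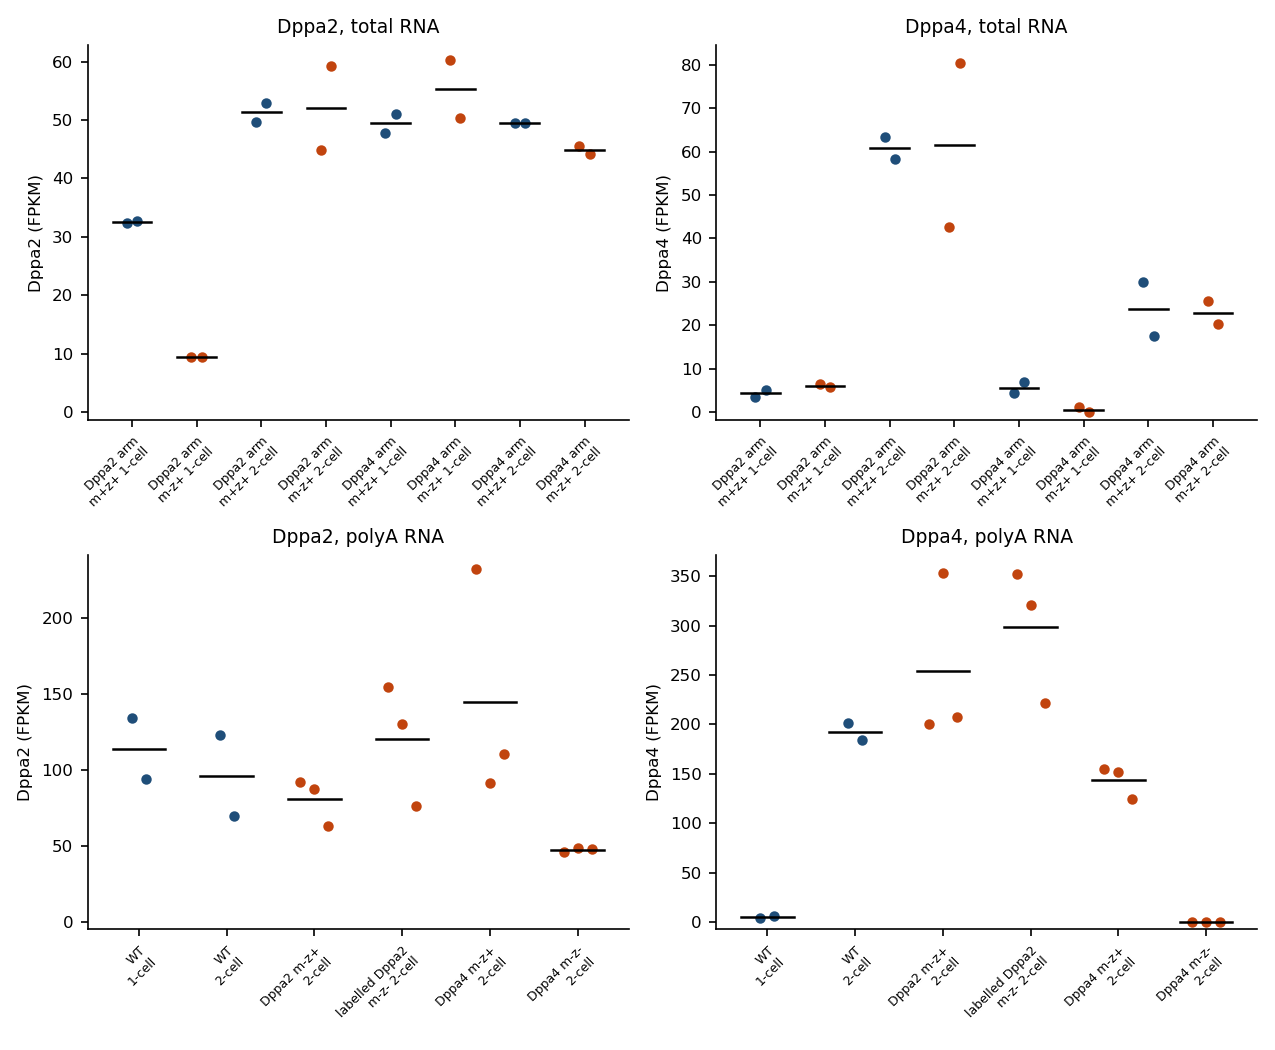
FPKM of Dppa2 and Dppa4 (vertical axes) in each library of the total RNA and polyA tables, by group on the horizontal axes, with control and WT libraries in blue, mutant libraries in red and the group mean as a line. Dppa4 lies between 0 and 0.15 FPKM in the 3 Dppa4 m-z- libraries, and Dppa2 lies between 76.5 and 155 FPKM in the 3 libraries labelled Dppa2 m-z-.

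The change from the 1-cell to the 2-cell stage in control embryos was examined for rises and falls in RNA level as the embryo takes over transcription. FPKM gives a share of the RNA in a library. A rise therefore does not by itself show new transcription, nor a fall the clearance of inherited RNA. In the Dppa2-arm controls, oocyte transcripts were lost and 2-cell genes appeared. The germ-cell RNA-binding gene Zar1l (chromosome 5, 150507055 to 150518164) fell from 195 ± 13.7 to 9.75 ± 1.86 FPKM (SD, n = 2 each; log2 change -4.19, SE 0.16, limma adjusted p = 8.46e-09). Ooep, a subcortical maternal complex gene, fell by 4.29 on the log2 scale. The 2-cell gene Tdpoz1 (chromosome 3, 93669333 to 93676310) rose from 0.0239 ± 0.0113 to 37.5 ± 8.29 FPKM (log2 change 5.22, SE 0.27, limma adjusted p = 2.57e-08), and the homeobox gene Obox6 rose by 6.31. Of 15068 genes tested, 4783 rose and 4498 fell at an adjusted p under 0.05. With TPM scaling the split was 3750 against 5802, and the median of all genes shifted by -0.30.

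Gene lists were then tested in the Dppa2-arm controls. Of 46 maternal transcripts, 42 fell and 2 rose (median -2.06, camera adjusted p = 2.69e-12), led by Ooep, Zar1l, Nlrp9b and Oog4. Of 40 2-cell genes, 33 rose and 4 fell (median 3.03, camera adjusted p = 5.24e-09), among them Usp17lb and Spz1. The Obox family divided: Obox3, Obox6 and Obox8 rose, and 4 members fell, among them Obox2 from 630.4 to 35.8 FPKM, so the list median was -2.14 and its mean 0.69. Of 59 ribosomal protein genes, 36 rose and 4 fell (median 1.29, camera adjusted p = 0.000142), led by Rps19, Rpsa and Rplp1. Ribosome biogenesis genes rose in 28 of 57 cases, including Nop2, and fell in 11 (median 0.69, camera adjusted p = 0.047). All 13 mitochondrially encoded genes rose (median 1.67, camera adjusted p = 3.43e-05), mt-Nd4l from 494 to 1886 FPKM. Preimplantation factors rose in 17 of 29 cases, including Klf5 and Zfp42, and fell in 4 (camera adjusted p = 0.0104). With an estimated correlation between members none of these lists passed: the smallest adjusted p was 0.329 with an estimated correlation, for the maternal transcripts.

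Smaller groups of genes also changed with stage in these controls. Genes of the p53 response rose in 12 of 21 cases, including Sesn2, Cdkn1a and Gadd45a, and fell in 3 (camera adjusted p = 0.0109). Imprinted genes rose in 15 of 23 cases, including Zrsr1, and fell in 2 (camera adjusted p = 0.0142). All 7 Y-linked genes measured rose, among them Eif2s3y and Uty (camera adjusted p = 0.0105). None of these 3 lists held, with an adjusted p of 0.518, 0.423 and 0.423 with an estimated correlation. Lists whose members moved both ways were the proteasome (10 rose, with Psme1; 20 fell, with Psma7 from 184 to 10.2 FPKM), splicing (16 rose; 20 fell, with Prpf6 and Lsm3) and translation factors (14 rose, with Eif1a and Eif3a; 9 fell). Heat shock genes rose in 11 cases, with Hspb1 and Cct6a, and fell in 8. Germline genes rose in 14 cases, with Trap1a and Hormad1, and fell in 6. Genes of chromatin and DNA methylation rose in 12 cases, with Kdm5b and Hdac1, and fell in 17, with Uhrf1. Cell cycle genes rose in 11 cases, with Ccne1 from 3.18 to 174 FPKM, and fell in 14, with Ttk and Cdc25a. Cumulus and granulosa markers rose in 2 and fell in 3 of 7 cases. Of 8 sperm transcripts only Prm2 and Hspa4l fell and none rose, with a median of 0.45 and a mean of -0.08. Among 6 measured neighbours of the Dppa2 and Dppa4 locus, Morc1 rose, and Pvrl3, C330027C09Rik and Myh15 fell. Camera gave no adjusted p under 0.05 for the Obox family or for any list here from the proteasome to the locus neighbours.

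Dppa4-arm controls gave the stage change on a B6 background. Zfp352, a 2-cell gene (chromosome 4, 90218820 to 90225702), rose from 0.334 ± 0.0759 to 76.7 ± 11.5 FPKM (n = 2 each; log2 change 5.86, SE 0.24, limma adjusted p = 1.10e-08). Among the genes that fell were Zar1l by 3.54 and Bms1 by 3.72 on the log2 scale, and the chaperone Hsp90aa1 from 1432 to 136.5 FPKM. In all, 3755 genes rose and 3649 fell, or 3087 and 4834 with TPM scaling, which shifted the median of all genes by -0.24. Of the 2-cell genes 35 rose and 4 fell (median 3.8, camera adjusted p = 2.30e-13), and of the maternal transcripts 37 fell and 2 rose (median -1.35, camera adjusted p = 1.90e-10). Each had an adjusted p of 0.196 with an estimated correlation. Proteasome genes fell in 20 of 38 cases and rose in 3 (camera adjusted p = 0.00135), with an adjusted p of 0.486 with an estimated correlation. Of 57 ribosome biogenesis genes 18 rose and 17 fell (median 0.09, camera adjusted p = 0.992). Ribosomal protein genes rose in 26 of 59 cases and fell in 9 (median 0.65, camera adjusted p = 0.0125). All 13 mitochondrially encoded genes rose (camera adjusted p = 4.73e-07). Preimplantation factors rose in 19 of 29 cases and fell in 3 (camera adjusted p = 0.000476). The p53 response, Y-linked, imprinted and splicing lists also passed camera. No list here passed with an estimated correlation. The 2-cell libraries of these controls differed in their stage markers, as given under Other observations.

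PolyA RNA of WT embryos gave the same comparison for polyadenylated transcripts. Ribosomal protein genes rose almost throughout: 56 of 59 rose and 1 fell (median 2.89, camera adjusted p = 2.00e-25), with Rps19 going from 3.28 ± 1.92 to 414 ± 40.7 FPKM (n = 2 each; log2 change 6.67, SE 0.32, limma adjusted p = 2.23e-10). This list held with an adjusted p of 0.0221 with an estimated correlation. The maternal transcripts held too, 31 of 46 having fallen and 2 risen, Ooep among the falls from 1312 to 49.3 FPKM (camera adjusted p = 1.88e-16, and an adjusted p of 0.0173 with an estimated correlation). Among 39 2-cell genes 30 rose and 2 fell, Usp17lb by 6.42 (camera adjusted p = 6.19e-13, and an adjusted p of 0.082 with an estimated correlation). Of 5 blood cell genes 4 rose, including Hba-a2 and Cd74 (camera adjusted p = 0.0137, and an adjusted p of 0.544 with an estimated correlation). In all 3225 genes rose and 1559 fell of 18506 tested, or 2805 and 2355 with median-ratio scaling. The total of 4784 dropped to 2762 without WT 1-cell replicate 1, to 2802 without WT 1-cell replicate 2 and to 3187 without WT 2-cell replicate 1. Across 13916 genes the WT polyA log2 changes correlated with those of the total RNA controls at r = 0.809 for the Dppa2 arm and 0.775 for the Dppa4 arm; genes are not independent replicates.

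The stage change of m-z+ embryos was set beside that of their controls. This asked whether embryos labelled as lacking the maternal supply of either gene still activate their genome. At the 1-cell stage the loss of Dppa2 RNA was partial, and that of Dppa4 RNA did not pass. Protein was not measured, so kept activation does not show that either factor is dispensable. Activated and cleared genes were defined in WT polyA libraries, which none of these total RNA comparisons use. The names stand for a rise or a fall in level between stages, and new transcription was not measured. In the Dppa2 arm, the 2311 activated genes rose by a median log2 of 2.02 in controls and 1.89 in m-z+ embryos, with 1900 and 1796 of them passing. The 946 cleared genes changed by medians of -2.18 and -2.07. Of the genes that rose in Dppa2-arm controls 3736 (78.1%) also rose in m-z+ embryos, and of those that fell 3652 (81.2%) also fell, where independent lists would share 1380 and 1279. Both groups went from the 1-cell to the 2-cell stage, so sharing above independence is likely with any genotype. It is no measure of kept activation. In the Dppa4 arm the activated genes changed by medians of 1.56 and 1.57 and the cleared genes by -1.64 and -1.72. The 2 control 2-cell libraries of this arm were unlike in their activated and cleared medians, as given under Other observations. The near-equal values thus rest on an average of unlike libraries. Of the control's rises and falls in this arm 3235 (86.2%) and 3193 (87.5%) were shared, where independent lists would share 950 and 912. The log2 changes of control and m-z+ embryos correlated across genes at r = 0.925 in the Dppa2 arm and 0.955 in the Dppa4 arm, where genes are not independent replicates. In m-z+ embryos 4346 genes rose and 4286 fell in the Dppa2 arm (3794 and 5098 with TPM scaling), and 3812 and 3767 in the Dppa4 arm (3146 and 5019).

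The difference between those stage changes was tested directly. For Dppa2 itself it was 1.69 (SE 0.22, limma adjusted p = 0.0628), with 52.0 ± 10.2 FPKM in m-z+ and 51.3 ± 2.31 FPKM in control embryos at the 2-cell stage (n = 2 each). No gene passed in the Dppa2 arm (0 in limma; 1299 at an unadjusted p under 0.05, where chance gives 753). That count became 154 without m-z+ 2-cell replicate 2, 24 without control 2-cell replicate 2, 12 without control 2-cell replicate 1, 6 without m-z+ 2-cell replicate 1, 4 without m-z+ 1-cell replicate 2 and 1 without m-z+ 1-cell replicate 1. In the Dppa4 arm 1 gene passed, the microRNA model Mir8092, and 2 without m-z+ 1-cell replicate 1 or m-z+ 2-cell replicate 2. As a list, maternal transcripts fell less in level between stages in Dppa2 m-z+ embryos (median difference 0.28, 33 of 46 positive, camera adjusted p = 0.00172, 4 higher and 1 lower adjusted over the list alone). The list did not pass with an estimated correlation (adjusted p = 0.797 with an estimated correlation).

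**Figure D2:**
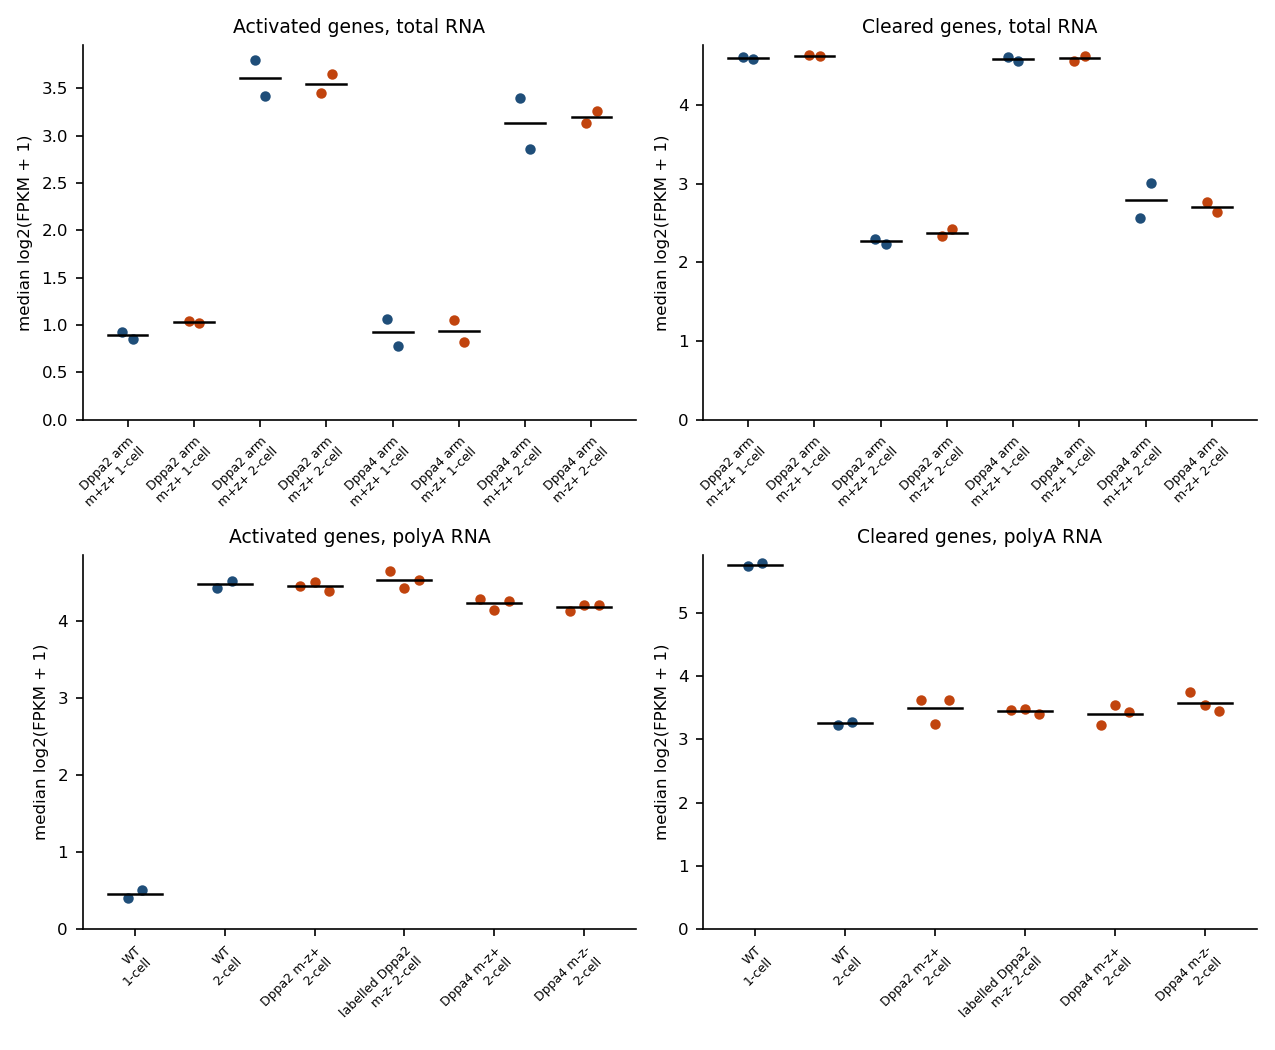
Median log2(FPKM + 1) per library (vertical axes) of genes activated and cleared between the stages, in total RNA and polyA RNA, by group on the horizontal axes, with control and WT libraries in blue, mutant libraries in red and the group mean as a line. For total RNA the genes were chosen in WT polyA libraries and for polyA RNA in both total RNA control arms. In total RNA the m-z+ group means followed their controls, with activated medians of 2.02 and 1.89 between stages in the Dppa2 arm and 1.56 and 1.57 in the Dppa4 arm. The 2 Dppa4-arm 2-cell controls differed from each other.

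At the 1-cell stage, before most embryonic transcription, 5 genes besides Dppa2 passed between Dppa2 m-z+ embryos and controls. Dppa2 RNA was lowered but not absent, at 9.38 and 9.52 FPKM, so the maternal genotype in the label showed as a partial fall. Lingo2, a gene for a neuronal transmembrane protein (chromosome 4, 35706647 to 36951747), fell from 9.14 ± 2.18 to 1.26 ± 0.191 FPKM (n = 2 each; log2 change -2.15, SE 0.30, limma adjusted p = 0.0377). At the 2-cell stage Lingo2 ran the other way, at 1.26 and 1.83 FPKM in controls and 1.92 and 5.04 FPKM in m-z+ embryos. The Dppa4-arm total RNA libraries held 9.45 to 11.7 FPKM of it. The small nuclear RNA model Gm22973, named after its values were seen, averaged 83.2 FPKM in controls and was listed at 0 in both m-z+ libraries (limma adjusted p = 0.000701). It passed at the 2-cell stage as well, at 16.7 FPKM in m-z+ embryos against 301 FPKM in controls (limma adjusted p = 0.0095). The immunoglobulin segment Ighv1-44 was listed at 0 in both controls and measured 2.03 ± 0.26 FPKM in m-z+ embryos (limma adjusted p = 0.0408). Of 15068 genes 2 rose and 4 fell, and 459 had an unadjusted p under 0.05, where chance gives 753. The spread in this fit was shared with the 2-cell libraries, whose replicates correlated less closely. The number of passing genes is therefore not directly comparable with that at the 2-cell stage. The count was 2 without either control replicate, 3 without m-z+ replicate 1, 6 without m-z+ replicate 2 and 0 in limma when only the 4 compared libraries were fitted (1109 at an unadjusted p under 0.05). Dppa2 and Gm22973 kept their call without each replicate, and the other four lost it each time. Among genes that did not pass, the mitochondrial enzyme gene Pdss2 measured 14.4 against 31.7 FPKM (limma adjusted p = 0.438) and Mocs2 18.7 against 8.34 FPKM (limma adjusted p = 0.664). Ribosomal protein genes shifted by a median of 0.21 (52 of 59 positive, camera adjusted p = 0.00243) and ribosome biogenesis genes by 0.18 (47 of 57 positive, camera adjusted p = 0.00689), with none passing singly or adjusted over the list alone. Both lists had an adjusted p of 0.898 with an estimated correlation.

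At the 2-cell stage the question was whether the embryo's transcription depends on the maternal Dppa2 allele. Protein inherited from the egg was not measured, and Dppa2 RNA in m-z+ embryos was near the control level by then. The signalling adaptor gene Crk (chromosome 11, 75679259 to 75706908) rose in Dppa2 m-z+ embryos from 47.2 ± 3.56 to 121 ± 24.7 FPKM (n = 2 each; log2 change 1.33, SE 0.16, limma adjusted p = 0.00951). The G-protein subunit gene Gng5 rose from 9.87 ± 0.165 to 28.9 ± 6.19 FPKM (log2 change 1.45, SE 0.22, limma adjusted p = 0.0225). The oocyte-secreted protein gene Oosp1 rose from 235 ± 45.2 to 427 ± 17.6 FPKM, the SMN-complex gene Gemin7 from 1.98 ± 1.09 to 12.9 ± 1.56 FPKM and the SAGA-complex gene Tada1 from 4.08 ± 0.18 to 11.4 ± 0.755 FPKM. Falls were seen for the arginine methyltransferase gene Prmt7 (from 3.96 ± 0.0959 to 0.527 ± 0.456 FPKM), the peroxisome gene Pex10 (from 2.15 to 0.182 FPKM), Crabp1 (from 3.92 to 0.783 FPKM), Cpne8 (from 4.10 to 0.923 FPKM) and the small nucleolar RNA Snora26 (from 25.3 ± 3.08 to 0.445 ± 0.373 FPKM). In all 10 genes rose and 18 fell, and 1932 had an unadjusted p under 0.05. Gene models shorter than 200 bases made up 7 of the 26 found in the annotation (26.9%), against 3.95% of the genes tested. The count was 26 without m-z+ replicate 1, 151 without control replicate 1, 220 without control replicate 2 and 465 without m-z+ replicate 2. Only 8 of the 28 remained without m-z+ replicate 1, among them Crk, Gng5 and Pex10. No gene passed with array weights, with a replicate block or when only the 4 compared libraries were fitted (688, 1875 and 613 in limma at an unadjusted p under 0.05).

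Lists in the same comparison moved by small amounts. Maternal transcripts stood higher in Dppa2 m-z+ 2-cell embryos by a median of 0.25 (38 of 46 positive, camera adjusted p = 0.000696); Oosp1 passed over all genes, and 10 were higher and 2 lower adjusted over the list alone. All 7 Obox genes leaned upward (median 0.56, camera adjusted p = 0.0152), and 2-cell genes had a median of 0.24 (31 of 40 positive, camera adjusted p = 0.0189), both lost with a pseudocount of 0.1 and with TPM scaling. Adjusted p-values were 0.864, 0.782 and 0.932 with an estimated correlation for the 3 lists. Zfp352 measured 93.5 ± 7.68 against 76.3 ± 0.868 FPKM (limma adjusted p = 0.668). The activated genes had a median of -0.03 against 0 for other genes (camera adjusted p = 0.574), and the cleared genes 0.10 against -0.01 (camera adjusted p = 0.00731, and an adjusted p of 0.818 with an estimated correlation).

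Dppa4 m-z+ embryos were examined in the same way on their own background. At the 1-cell stage Mir8092 (chromosome 19, 40894703 to 40894789, 87 bases) rose from 0.138 ± 0.0176 to 8.97 ± 4.05 FPKM (n = 2 each; log2 change 3.07, SE 0.36, limma adjusted p = 0.0203). No other gene passed, and 192 had an unadjusted p under 0.05. The count was 0 in limma without control replicate 1 or m-z+ replicate 2 and 2 without m-z+ replicate 1, and Mir8092 also lost its call without control replicate 2. The actin-linked gene Gas2l3 measured 10.8 against 28.0 FPKM (limma adjusted p = 0.112) and Pcbp3 34.7 against 17.7 FPKM (limma adjusted p = 0.296). The 2 control libraries of the 2-cell stage differed in their stage markers, as given under Other observations. At the 2-cell stage no gene passed in limma, 402 having an unadjusted p under 0.05, where chance gives 753. The count was 1 without control replicate 1 and 3 without m-z+ replicate 2. Among the smallest p-values were the complex I assembly gene Ndufaf4, at 16.2 ± 2.56 against 43.2 ± 6.54 FPKM (limma adjusted p = 0.562), and Mir5136 (log2 difference 1.71, limma adjusted p = 0.234). None of the 20 lists passed at either stage; ribosomal protein medians were 0.07 at both. Activated genes had a median of 0.04 against 0 for other genes at the 2-cell stage (camera adjusted p = 0.259), and cleared genes -0.06 against 0.01 (camera adjusted p = 0.0639).

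The arms were compared to ask whether the maternal mutations of the 2 genes had a shared effect, with no control library in common. Log2 differences of m-z+ against control correlated across genes at r = -0.10 at the 1-cell and 0.01 at the 2-cell stage, where genes are not independent replicates. The difference between arms passed for Dppa2, Mir8092 and Gm22973 at the 1-cell stage (319 genes at an unadjusted p under 0.05) and for Gm15056 at the 2-cell stage (1094 genes). The last 2 named are predicted models, picked out after their values were seen.

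Embryos lacking both maternal and zygotic Dppa4 were set against embryos lacking the maternal allele alone. By their labels these differ in the zygotic allele and are all B6. The labels do not say whether both groups came from the same crosses or collections. Apart from Dppa4, only the predicted models Gm14058 and Gm6773 passed, and they are named after their values were seen. Gm14058 was listed at 0 in the 3 m-z- libraries and at 17, 15.5 and 12.9 FPKM in the 3 m-z+ libraries (limma adjusted p = 5.92e-05); its sequence matched Dppa4 at 98.9% over 735 bases, so its own level is uncertain. Gm6773 was listed at 0 in the m-z- libraries and at 2.67, 3.88 and 3.85 FPKM in m-z+ (limma adjusted p = 0.0237), and at 0 in both WT 2-cell libraries. No gene rose, and 1296 had an unadjusted p under 0.05, where chance gives 925. The count was 5 without m-z- replicate 3 and 1, Dppa4, when only the 6 compared libraries were fitted. Genes that did not pass included the translation initiation gene Eif2s3x (12.2 ± 0.661 against 44.3 ± 3.75 FPKM, limma adjusted p = 0.399), the histone chaperone gene Hira (1.16 against 9.53 FPKM, limma adjusted p = 0.437) and the 2-cell gene Tcstv3 (410 ± 61.4 against 191 ± 52.4 FPKM, limma adjusted p = 0.661).

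Genes of protein synthesis stood lower in Dppa4 m-z- than in Dppa4 m-z+ embryos as groups. Ribosomal protein genes had a median of -0.36 (7 of 59 positive, camera adjusted p = 1.80e-07). Translation factors had a median of -0.41 (camera adjusted p = 2.44e-06), ribosome biogenesis genes -0.34 (4.70e-05), proteasome genes -0.31 (0.000269), heat shock genes -0.26 (0.0314) and splicing genes -0.10 (0.0314). No member passed over all genes, and only 1 translation factor was lower adjusted over the list alone. The 2-cell genes stood higher (median 0.30, camera adjusted p = 0.0314, 2 higher adjusted over the list alone), a call lost with a pseudocount of 0.1, with TPM and with median-ratio scaling. The smallest of these lists' adjusted p-values was 0.362 with an estimated correlation. Activated genes had a median of -0.06 against 0.09 for other genes (camera adjusted p = 0.0399, and an adjusted p of 0.203 with an estimated correlation). Cleared genes had 0.18 against 0.08 (camera adjusted p = 0.106).

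The libraries labelled Dppa2 m-z- were compared with Dppa2 m-z+ embryos for the same question, with a genotype that Dppa2 RNA did not bear out. The predicted model Gm16027, named after its values were seen, fell by 2.49 on the log2 scale (limma adjusted p = 0.0414); no other gene passed, and 1415 had an unadjusted p under 0.05. The count was 32 without m-z+ replicate 1, 3 without m-z+ replicate 2, 2 without labelled m-z- replicate 1, and 0 in limma without m-z+ replicate 3, labelled m-z- replicate 2 or labelled m-z- replicate 3. The translation regulator gene Cpeb4 measured 4.70 ± 2.29 against 22.5 ± 9.25 FPKM and did not pass (limma adjusted p = 0.185). As labelled, the lists ran opposite to those in the Dppa4 arm, and with the 2 labels exchanged each would turn its sign and run the same way. Ribosomal protein genes had a median of 0.38 (55 of 59 positive, camera adjusted p = 3.64e-08). Ribosome biogenesis genes had 0.32 (48 of 57 positive, 0.000133), translation factors 0.27 (0.00715), splicing genes 0.19 (0.0146) and proteasome genes 0.18 (0.0362), and no member passed singly or adjusted over the list alone. None held, the smallest adjusted p being 0.416 with an estimated correlation. Tested between the arms, the ribosomal protein difference was 0.72 as labelled (camera adjusted p = 9.90e-13, and an adjusted p of 0.112 with an estimated correlation) and 0.00 with the labels exchanged (camera adjusted p = 0.96). The latter follows from the opposite signs of medians of similar size and is no evidence for an exchange. Blood cell genes had a median of 1.46 (camera adjusted p = 0.0314, 1 higher adjusted over the list alone), a call lost without labelled m-z- replicate 3, the only polyA library with beta-globin transcripts (Hbb-bs and Hbb-bt). Activated genes had 0.08 against -0.08 for other genes (camera adjusted p = 0.00812, and an adjusted p of 0.10 with an estimated correlation). With TPM scaling their median was -0.01 (camera adjusted p = 0.0512). Between the arms these log2 differences correlated across genes at r = -0.16, genes not being independent replicates, and differed for Dppa4, Gm14058 and Gm4707 (1896 genes in limma at an unadjusted p under 0.05).

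**Figure D3:**
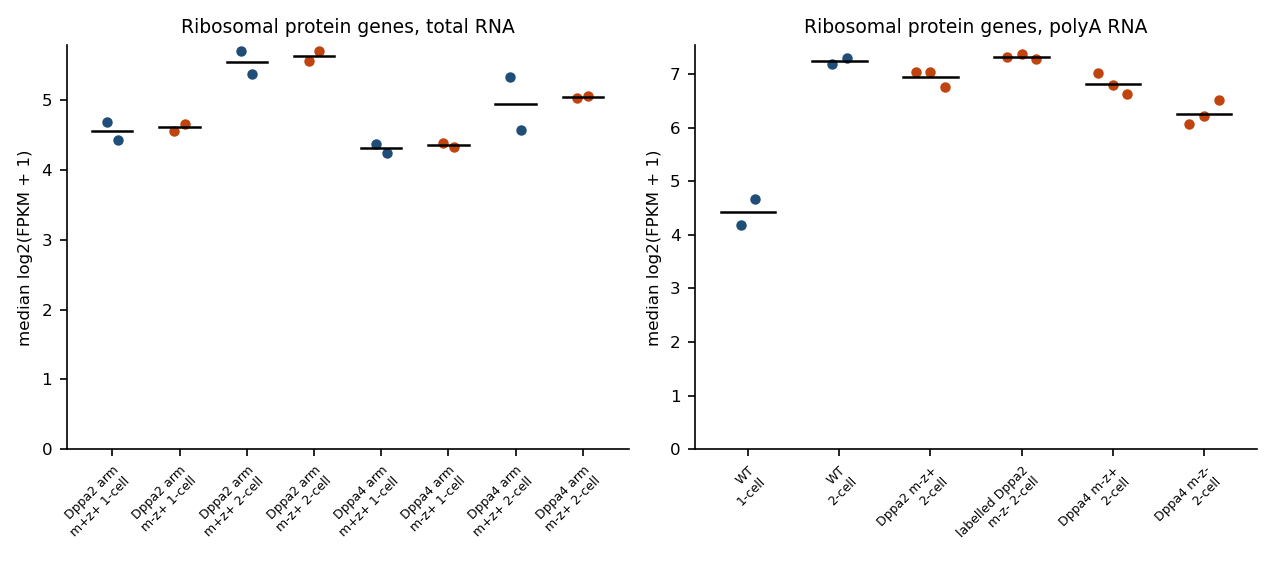
Median log2(FPKM + 1) of the 59 ribosomal protein genes per library (vertical axes) in total RNA and polyA RNA, by group on the horizontal axes, with control and WT libraries in blue, mutant libraries in red and the group mean as a line. The 3 Dppa4 m-z- libraries lie at 6.06, 6.21 and 6.51 and the 3 libraries labelled Dppa2 m-z- at 7.32, 7.37 and 7.27.

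Dppa4 mutants were also compared with WT 2-cell embryos of the same strain. The labels do not say whether these were prepared or sequenced together, and no batch was modelled. The adhesion receptor gene Selp stood higher in Dppa4 m-z- embryos, at 30.9 ± 3.40 (n = 3) against 0.837 ± 0.573 FPKM (n = 2; log2 difference 4.15, SE 0.58, limma adjusted p = 0.0087). The histone mRNA exonuclease gene Eri1 measured 20.5 ± 4.81 against 2.50 ± 3.27 FPKM and Tmem171 40.0 ± 12.7 against 5.27 ± 1.47 FPKM. In WT 1-cell embryos Selp measured 35.3 and 25.35 FPKM and Eri1 13.9 and 11.25 FPKM. Dppa4 m-z+ embryos held 8.88, 21.5 and 10.8 FPKM of Selp and 14.1, 15.0 and 14.2 FPKM of Eri1. The WT 2-cell libraries thus held less of both genes than the WT 1-cell and the Dppa4 m-z+ libraries. Eri1 was also higher in Dppa2 m-z+ embryos (3.37) and in those labelled Dppa2 m-z- (3.34) against the same 2 WT libraries. The stathmin gene Stmn3 fell from 54.4 ± 10.4 to 8.27 ± 6.07 FPKM (log2 change -2.77, SE 0.48, limma adjusted p = 0.0325), and Dppa4 fell by 7.53. In all 4 genes rose and 8 fell, with 1976 at an unadjusted p under 0.05. The count was 3 without WT replicate 1, 2 without m-z- replicate 1, 2 without m-z- replicate 2, 20 without m-z- replicate 3 and 1 when only the compared libraries were fitted. In Dppa4 m-z+ embryos no gene passed in limma (1230 at an unadjusted p under 0.05), or 2 without WT replicate 2 and 1 without m-z+ replicate 2. The 1000 activated genes stood lower than WT in m-z- embryos (median -0.38 against 0 for other genes, camera adjusted p = 2.63e-05) and the 455 cleared genes higher (0.28, camera adjusted p = 0.000137). Both passed at an adjusted p of 0.014 and 0.0302 with an estimated correlation. The sets against WT were not tested with other settings or without single libraries. In m-z+ embryos these medians were -0.30 and 0.10 (camera adjusted p = 0.00353 for each, and an adjusted p of 0.0762 with an estimated correlation). Against the same WT libraries, activated genes had a median of -0.14 in Dppa2 m-z+ embryos (camera adjusted p = 0.0131, and an adjusted p of 0.123 with an estimated correlation). In those labelled Dppa2 m-z- it was -0.02 (camera adjusted p = 0.86). The shift from WT was thus not particular to Dppa4 m-z- embryos, whose median against Dppa4 m-z+ was -0.06.

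Relative to WT, ribosomal protein genes had a median log2 difference of -0.84 in Dppa4 m-z- embryos (1 of 59 positive, camera adjusted p = 6.24e-19, 29 lower adjusted over the list alone) and -0.46 in m-z+ embryos (0 of 59 positive, camera adjusted p = 1.73e-07, 3 lower adjusted over the list alone). Proteasome genes had a median of -0.60, translation factors -0.55, ribosome biogenesis genes -0.53 and splicing genes -0.32 in m-z- embryos. The 2-cell genes stood higher by 0.73 (28 of 39 positive, camera adjusted p = 8.98e-06, 1 higher adjusted over the list alone) and maternal transcripts by 0.48 (35 of 46 positive, camera adjusted p = 3.41e-05, 4 higher adjusted over the list alone). No list held: the smallest adjusted p was 0.113 with an estimated correlation in m-z- and 0.469 in m-z+ embryos. Both comparisons use the same 2 WT libraries, so their values are not independent.

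Dppa2-arm embryos differed from WT in strain as well as genotype, and all those in polyA RNA were labelled as Dppa2 mutants. Calhm3, an ion channel gene, was listed at 0 in all 6 Dppa2-arm polyA libraries and measured 26.9 and 70.1 FPKM in WT. In total RNA of 2-cell controls, which carry no mutation, it was listed at 0 in both Dppa2-arm libraries and at 0.61 and 3.94 FPKM in the Dppa4 arm. The lysophospholipase-like gene Lyplal1 stood higher in Dppa2 m-z+ embryos, at 39.2 ± 4.41 (n = 3) against 3.21 ± 1.38 FPKM (n = 2; log2 difference 3.29, SE 0.38, limma adjusted p = 0.000963). In total RNA of 2-cell embryos it measured 5.44 and 7.47 FPKM in Dppa2-arm controls and 15.2 and 6.57 FPKM in Dppa2 m-z+ embryos, against 2.69 and 3.13 FPKM in Dppa4-arm controls, and at the 1-cell stage 20.8 and 19.7 FPKM in Dppa2-arm against 5.65 and 5.14 FPKM in Dppa4-arm controls. The galactosyltransferase gene B4galt4 was higher by 3.75 and the cytohesin gene Cyth1 lower by a log2 difference of -1.84. In all 10 genes were higher and 11 lower in Dppa2 m-z+ embryos, a total of 21 that became 2 without WT replicate 1 and 9 without WT replicate 2. In the libraries labelled Dppa2 m-z- 7 were higher, with Lyplal1 and Eri1, and 11 lower, a total of 18 that became 1 without WT replicate 1, 10 without WT replicate 2, 5 without labelled m-z- replicate 2 and 9 without labelled m-z- replicate 3. No gene passed in either comparison when only the compared libraries were fitted (1075 and 1187 in limma at an unadjusted p under 0.05). Ribosomal protein genes had a median of -0.34 in Dppa2 m-z+ embryos (3 of 59 positive, camera adjusted p = 1.88e-05, and an adjusted p of 0.966 with an estimated correlation). In the libraries labelled Dppa2 m-z- no list passed.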

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

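The tests of Dppa2 RNA in the libraries labelled Dppa2 m-z-, the tests matching ribosomal protein genes on coding transcript length, the tests of their medians under scaling without centring, the contrasts between the arms and those with exchanged labels were chosen after the results were seen; the other tests were written down first, though labelled Dppa2 m-z- replicate 3 was picked for its test after its globin values were seen.

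The difference between genotypes, as labelled, was unlike in the Dppa2 and the Dppa4 arm for 7 genes, and unlike between the stages of an arm for 1. Of these, Dppa2 (-1.83 between arms at the 1-cell stage, limma adjusted p = 0.0127) and Dppa4 (7.36 in polyA RNA, limma adjusted p = 5.21e-08) are the targeted genes. Mir8092, an 87-base model, differed by -5.11 between arms at the 1-cell stage and by -5.07 between the stage changes of Dppa4 m-z+ and control embryos. The other predicted models were Gm22973 (-5.94 at the 1-cell stage), Gm15056 (-4.49 at the 2-cell stage), and Gm14058 (4.16) and Gm4707 (-4.25) in polyA RNA. The polyA values for Dppa4, Gm14058 and Gm4707 rest on Dppa2-arm labels that Dppa2 RNA did not bear out. Maternal transcripts differed between arms at the 2-cell stage in total RNA by a median of 0.389, with an adjusted p of 0.999 with an estimated correlation.

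The libraries labelled Dppa2 m-z- held Dppa2 RNA in the range of the other polyA groups. Libraries labelled m-z+ would list Dppa2 near 0 after an exchange of labels with this group if the mutant allele made no RNA, and the lowest value there was 63.25 FPKM. RNA made from the mutant allele may account for the lowest value of 76.55 FPKM in the libraries labelled m-z-, as gene-level values do not tell alleles apart, and with such RNA an exchange stays open as well. A wrong genotype of all 3 embryos stays open too, and these cannot be told apart without the reads over the mutated bases.

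Gm14058 was listed at 0 in Dppa4 m-z- embryos and was higher in the Dppa2 arm's contrast by 4.16 than in the Dppa4 arm's. Its sequence matched a Dppa4 transcript at 98.91% over 735 bases, so reads shared with Dppa4 are a candidate explanation, consistent with its loss only where Dppa4 was lost. Gm6773, which fell in the same comparison, had no match to Dppa4, so shared reads would not account for it.

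Ribosomal protein genes had a median of 0.38 in the libraries labelled Dppa2 m-z- against Dppa2 m-z+ and -0.36 in Dppa4 m-z- against Dppa4 m-z+. The difference between arms was 0.7215 (camera adjusted p = 9.90e-13, and an adjusted p of 0.112 with an estimated correlation). It became -0.0044 with the Dppa2-arm labels exchanged (camera adjusted p = 0.96). That value follows from the opposite medians and cannot tell whether labels were exchanged. Genes matched on exon length and level had medians of 0.1514 (95% of 1000 draws from 0.0166 to 0.268) and -0.03145 (-0.22 to 0.0775), and genes matched on coding transcript length 0.08335 (-0.0424 to 0.223) and -0.0348 (-0.173 to 0.0767), which argues against length and level as the whole cause. Median-ratio scaling gave 0.4687 and -0.4055 and TPM scaling 0.2929 and -0.3563, which argues against these scalings as the whole cause, while the medians relative to all genes after median-ratio scaling, 0.4828 and -0.4545, decide nothing because centring takes out most of a factor per library. Without labelled Dppa2 m-z- replicate 3, the only polyA library with beta-globin transcripts, the Dppa2-arm median was 0.3796, which argues against that library. A difference in developmental timing between single embryos may contribute and was not tested, and an effect of the zygotic genotype stays open as a hypothesis, with its direction in the Dppa2 arm resting on labels that Dppa2 RNA did not bear out.

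Further lists differed between the arms in polyA RNA as labelled, none of which held with an estimated correlation (adjusted p from 0.112 to 0.323). They were ribosome biogenesis by a median of 0.6681, proteasome by 0.6159, translation factors by 0.5568, splicing by 0.3252, the Obox family by 0.3017, heat shock by 0.2174 and blood cells by 2.577. With the Dppa2-arm labels exchanged no list passed, the smallest camera adjusted p being 0.0842 for the 2-cell genes. Exchanging only turns the sign of the Dppa2-arm contrast, so this is no evidence for an exchange either.

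Counts of passing genes in the polyA comparisons of m-z- with m-z+ were set against all 10 splits of the 6 libraries of an arm into groups of 3, which are too few for a share under 0.05. In the Dppa4 arm the real split gave 3 genes and the highest other split 1, so that 1 of the 10 splits, the real one, gave as many. The 3 were the mutated gene Dppa4, Gm14058, which matched it in sequence, and Gm6773. The lead of the real split therefore shows little beyond the loss of Dppa4. In the Dppa2 arm the real split gave 1 gene and the highest other split 4, and 6 of the 10, the real one included, gave as many.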

How the results depend on the processing

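The restriction to gene models of at least 200 bases, the lists without labelled Dppa2 m-z- replicate 3, the contrasts between arms and those with the Dppa2-arm polyA labels exchanged were chosen after the data were seen; the other tests were planned. Of the genes, lists and sets followed singly, 1 changed sign with the labels kept: activated genes in the Dppa2-arm polyA comparison of m-z- with m-z+, with a median of -0.0125 under TPM scaling. With TPM scaling more genes fell than rose in the stage changes of total RNA: 3750 rose and 5802 fell in Dppa2 controls, 3794 and 5098 in Dppa2 m-z+, 3087 and 4834 in Dppa4 controls, and 3146 and 5019 in Dppa4 m-z+. Stage-change totals of rises and falls stayed within 1.5 times under each scaling, filter and pseudocount, though falls in WT polyA RNA went from 1559 to 2355 with median-ratio scaling, while the short counts for mutants moved; the cause was not tested except where fewer genes or libraries were fitted. Without a low-value filter the counts were 49 and 111 for Dppa2 m-z+ against control at the 1-cell and 2-cell stage, 18 and 54 for Dppa4, 6 and 5 for m-z- against m-z+ in the Dppa2 and Dppa4 arms, 21 and 27 for Dppa4 m-z+ and m-z- against WT, 41 and 30 for the Dppa2 arm against WT, and 41 and 19 for the difference in stage change in the Dppa2 and Dppa4 arms. With a pseudocount of 0.1 they were 1 for Dppa4 m-z+ against control at the 2-cell stage, 12 and 11 for the Dppa2 arm against WT and 2 for the stage difference of the Dppa2 arm, and the correlation between arms was -0.0617 at the 1-cell stage and -0.0914 in polyA RNA. TPM scaling gave 16 for Dppa2 m-z+ at the 2-cell stage and 5 for the stage difference of the Dppa2 arm. Median-ratio scaling gave 2 for Dppa4 m-z+ at the 1-cell stage, 5 for Dppa4 m-z+ against WT and 3 for the stage difference of the Dppa2 arm. Array weights gave 21 and 0 (688 at an unadjusted p under 0.05 in limma) for Dppa2 m-z+ at the 1-cell and 2-cell stage, 16 for Dppa4 m-z+ at the 1-cell stage, 5 for Dppa4 m-z+ against WT and 7535 for the WT stage change. For m-z- against m-z+ in the Dppa2 arm the count became 0 in limma with a pseudocount of 0.1 (1347 at an unadjusted p under 0.05), TPM (1436), median-ratio scaling (1366), array weights (1165), the replicate block (1209) and only the compared libraries (943). The replicate block, for which replicate numbers did not pair libraries, gave 2 and 0 (1875 at an unadjusted p under 0.05) for Dppa2 m-z+ at the 1-cell and 2-cell stage, 0 (194) for Dppa4 m-z+ at the 1-cell stage, 2 for Dppa4 m-z- against WT, and 5 and 2 for the Dppa2 arm against WT, in limma. Fitting only the compared libraries gave 0 and 0 (1109 and 613 at an unadjusted p under 0.05) for Dppa2 m-z+ at the 1-cell and 2-cell stage, 1 for Dppa4 m-z- against m-z+, 1 for Dppa4 m-z- against WT, 0 and 0 (1075 and 1187) for the Dppa2 arm against WT and 0 (416) for the stage difference of the Dppa4 arm, in limma. With only gene models of at least 200 bases Mir8092 was not tested, and the counts were 0 for Dppa4 m-z+ at the 1-cell stage (180 at an unadjusted p under 0.05 in limma) and 0 for the stage difference of the Dppa4 arm (250). In the 6 comparisons of m-z+ with control and of m-z- with m-z+, 18 lists and 3 sets passed camera, none of them (0 and 0) with an estimated correlation between genes, 17 lists without labelled Dppa2 m-z- replicate 3, and 1 set when activated and cleared genes were taken at a log2 change of 1.

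Leaving out 1 library at a time, the counts ranged from 2 to 6 and 26 to 465 for Dppa2 m-z+ against control at the 1-cell and 2-cell stage, 0 to 2 and 0 to 3 for Dppa4, 0 to 32 and 2 to 5 for m-z- against m-z+ in the Dppa2 and Dppa4 arms, 0 to 2 and 2 to 20 for Dppa4 m-z+ and m-z- against WT, and 2 to 28 and 1 to 13 for the Dppa2 arm against WT. Stage-change counts ranged from 7635 to 8819 in Dppa2 controls, 7216 to 8035 in Dppa2 m-z+, 5393 to 6994 in Dppa4 controls, 5501 to 6368 in Dppa4 m-z+ and 2762 to 3321 in WT polyA RNA, and the stage differences from 0 to 154 and 1 to 2. For each gene that passed between genotypes or in the stage differences, predicted models included, every refit was compared with the main fit. Dppa2 and Dppa4 were included at an unadjusted p under 0.05. Pairings of a gene with a left-out library stayed on the same side of the threshold in 245 cases, newly passed in 4 and lost the call in 209. With other settings these pairings numbered 374, 5 and 293. For lists and sets only 1 library was left out, labelled Dppa2 m-z- replicate 3, which kept 20 calls, strengthened 0 and lost 1. That library is not used in total RNA and reaches the Dppa4 arm only through the shared spread, so most of these calls could hardly change. No list or set was tested without any other library. Other settings kept 108 list and set calls, strengthened 0 and lost 42. With FPKM alone the depth behind a value is unknown, so no limit from counting could be given.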

Other observations

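Beta-globin transcripts were listed in a single polyA library. In labelled Dppa2 m-z- replicate 3, Hbb-bs stood at 378 FPKM and Hbb-bt at 118 FPKM, and both were listed at 0 in the other 15 polyA libraries. Hba-a1 measured 532 FPKM and Hba-a2 505 FPKM there, against 3.42 to 48.3 and 2.46 to 60.4 FPKM in the other 2-cell polyA libraries.

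The Y-linked translation factor gene Eif2s3y marked single embryos of each group. It measured 46.5 and 0 FPKM in WT 2-cell embryos, 64.0, 23.1 and 0 FPKM in Dppa2 m-z+, 31.3, 48.7 and 0 FPKM in those labelled Dppa2 m-z-, 33.6, 0 and 0 FPKM in Dppa4 m-z+, and 0, 21.1 and 50.8 FPKM in Dppa4 m-z- embryos, so each of these groups held at least 1 embryo with and 1 without Eif2s3y RNA. Xist, the X-inactivation RNA, reached 20.1 FPKM in Dppa2 m-z+ replicate 3, which had no Eif2s3y RNA.

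The 2 total RNA libraries of 2-cell Dppa4-arm controls differed in their stage markers. In replicate 2 the median log2(FPKM + 1) was 2.86 for activated genes, 3.01 for cleared genes and 4.57 for ribosomal protein genes, against 3.40, 2.56 and 5.33 in replicate 1. Mir8092 differed in opposite directions with genotype in the arms: in total RNA at the 1-cell stage it stood at 4.64 and 4.80 FPKM in Dppa2-arm controls and 0.17 and 0.65 FPKM in m-z+ embryos, against 0.15 and 0.13 FPKM in Dppa4-arm controls and 6.11 and 11.8 FPKM in m-z+ embryos. At the 2-cell stage each arm ran the other way, with 0.32 and 0.27 FPKM in Dppa2-arm controls and 1.59 and 3.28 FPKM in m-z+ embryos, against 6.40 and 3.57 FPKM in Dppa4-arm controls and 0.77 and 0.20 FPKM in m-z+ embryos. Of these comparisons of m-z+ with control, only that of the Dppa4 arm at the 1-cell stage passed (limma adjusted p = 0.0203).

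Calhm3 was listed at 0 in all 8 Dppa2-arm total RNA libraries. In the Dppa4 arm it measured 0.06, 0, 0.08 and 0 FPKM in the 4 total RNA libraries at the 1-cell stage and 0.61, 3.94, 0.55 and 4.05 FPKM in the 4 at the 2-cell stage. In polyA RNA it reached 69.9, 51.1 and 115 FPKM in Dppa4 m-z+ and 39.8, 61.7 and 112 FPKM in Dppa4 m-z- embryos.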
